A study of Homo sapiens with 6 samples.

How the data were processed

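Poly(A) RNA of RKO cells was sequenced in 6 libraries, 2 for each of the groups control, cTAZ KO and cTAZ putback, per the labels. The authors deposited a table of FPKM values per gene, with a gene type, for all 6 libraries. Per the submitters' processing notes HISAT2, featureCounts and the build hg38 were named, without versions; strand and the handling of multi-mapping reads were not given in the sources used here. No column of other samples was left unused.

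FPKM of whole reads are multiples of what 1 read is worth, so library totals and gene lengths were recovered from the deposited values. All 12621 tested genes gave whole reads in all 6 libraries within 0.02 reads, and 9 genes above 0 did not. The recovered reads made up 99.4% to 99.5% of each total, with a median of 473 reads per tested gene. FPKM are not counts, so the main test did not use these reads.

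Values were taken as log2(FPKM + 1). Genes with a mean FPKM of at least 1 were tested (10950 of type mRNA, 1090 ncRNA and 581 of other types), from 41762 listed, of which 19810 were at 0 in all libraries. limma 3.58.1 in R 4.3.3 fitted the 3 group means over all 6 libraries, with 3 residual degrees of freedom and 4.08 prior degrees of freedom, an intensity trend in the prior and two-sided tests. P-values were adjusted by Benjamini-Hochberg over all tested genes at a threshold of 0.05. Of 22 gene lists fixed, 21 had a tested member (the fibroblast list had 0) and were tested with camera at a preset inter-gene correlation of 0.01, adjusted within a comparison, with camera at an estimated correlation beside it, and with fry. The preset test called 21 of the 63 list and comparison pairs. With an estimated correlation 3 held: the interferon-stimulated genes in KO against control and in putback against KO, and the NF-kB list in KO against control.

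Groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took, per comparison, the 10 largest rises and 10 largest falls among symbols past the test whose libraries did not overlap, WWTR1, up to 4 members with the smallest p per list with a called member, 4 from the lists on interferon, antigen presentation, JAK-STAT and YAP/TAZ-TEAD whatever their p, and the 10 largest reversed genes. Genes singled out otherwise were chosen after their values were seen. Mitochondrial genes were matched under the symbols of the table. Positions and GC content came from GENCODE release 29 on hg38, for 11873 of the tested genes (94.1%).

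The test was tried on simulated data with 12621 genes, 200 of them changed in KO, and 1 dispersion (0.000912) shared by all genes. For KO against control, 77.3% of genes changed by 0.5 on the log2 scale were recovered, 97.0% at 1 and 100% at 2, with 6.6% of calls false. For putback against KO these were 75.8%, 97.0%, 100% and 4.2%. Genes called in the real data had median absolute log2 changes of 0.35 in KO against control, 0.313 in putback against KO and 0.358 in putback against control. These lie below the smallest simulated change of 0.5, so the simulated rates do not describe most of those calls. In the real data the spread differed between genes (4.08 prior degrees of freedom), and 2937 genes were called in KO against control. The simulated rates at 1 and 2, and of false calls, therefore need not hold for these data. Alternatives were other pseudocounts (0.1 and 5), filters, scalings, a replicate block, fits with 2 groups, a constant prior variance, each library left out, and a 2-fold minimum. Added after seeing the data were limma-voom on recovered reads, reads thinned to the smallest library, mRNA genes only, and a correction for GC content and length. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.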

Results

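RNA from RKO cells, a human colorectal cancer line, was sequenced in 6 poly(A) libraries. The labels give 3 groups of 2 libraries: control cells, cells labelled cTAZ KO and cells labelled cTAZ putback. cTAZ is a shortened form of the transcriptional co-activator TAZ, made from the gene WWTR1. The deposited values are FPKM per gene. Library totals recovered from those values were 10710500 and 11061662 reads in control, 10667589 and 13722502 in KO, and 17267439 and 17589254 in putback, so depth differed with the group. Of 41762 listed genes, 12621 had a mean FPKM of at least 1 and were tested. The labels do not say that replicates came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. Levels below are mean FPKM ± SD with n = 2 libraries, log2 changes are on the log2(FPKM + 1) scale, which understates the change of low genes, and adjusted p-values are from limma.

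WWTR1 (chromosome 3, 149517235 to 149736714, minus strand, hg38) was measured first, as the targeted gene. Its level was 14.3 ± 0.452 in control, 7.43 ± 0.409 in KO and 74.2 ± 1.18 in putback. It fell by 0.86 on the log2 scale in KO against control (adjusted p = 0.000139) and rose by 3.16 in putback against KO (adjusted p = 1.93e-06). It was 2.30 higher in putback than in control (adjusted p = 2.56e-06). The table holds a single value per gene, so reads of cTAZ and of full-length TAZ were not separated.

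**Figure D1:**
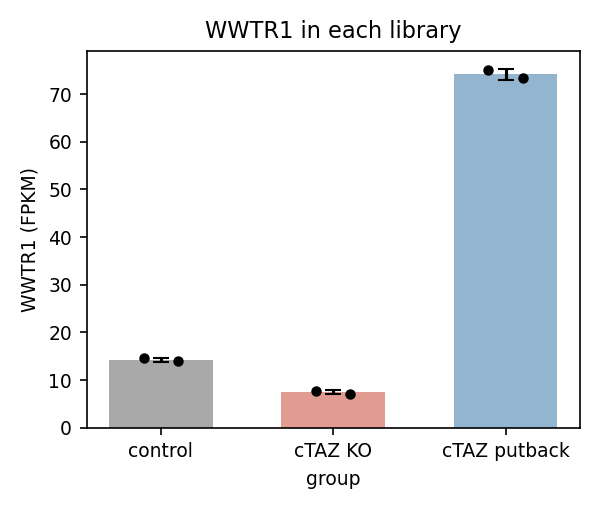
WWTR1 level in FPKM (vertical axis) in the 3 groups, with bars at the mean, error bars of 1 SD and points for the 2 libraries of each group. The putback libraries lie near 74.2, the control libraries near 14.3 and the KO libraries near 7.43.

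The first comparison asked what differed in the cells labelled cTAZ KO; cTAZ has been studied as a regulator of JAK-STAT signalling. Interferon-stimulated genes, the antiviral genes switched on by interferon signalling, were higher in KO than in control for all 40 measured members (also 40 adjusted over the list alone), with a median log2 change of 1.40. IFITM1, a membrane protein that restricts virus entry, rose from 10.03 ± 2.58 to 378 ± 2.91. IFI6 rose from 13.8 ± 0.996 to 338 ± 16.03, and OAS2, an RNA-sensing 2'-5' oligoadenylate synthetase, rose from 0.893 ± 0.069 to 38.1 ± 1.69. ISG15, a ubiquitin-like modifier, rose from 160.4 ± 2.003 to 618 ± 2.81. The list stood above other genes in the camera test (adjusted p = 3.39e-40) and with an estimated correlation (adjusted p = 0.0391).

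**Figure D2:**
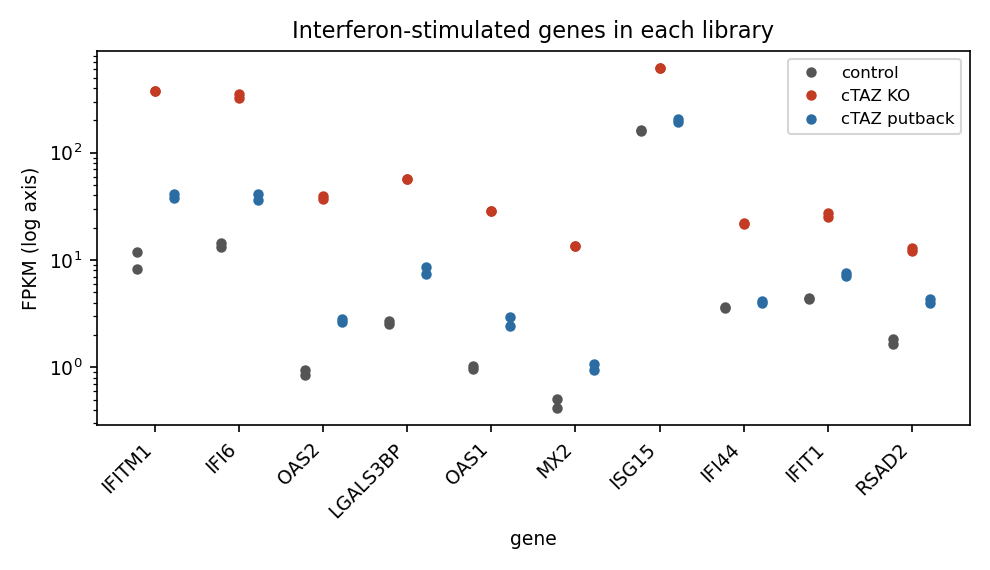
FPKM on a log axis (vertical) of 10 interferon-stimulated genes (horizontal), with a point for each of the 6 libraries coloured by group. For each gene the KO points lie highest, as for IFITM1 at 378 in KO, 39.9 in putback and 10.03 in control.

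More of this group stood among the top genes. LGALS3BP, a secreted glycoprotein, rose from 2.60 ± 0.117 to 56.4 ± 0.012. OAS1 rose by 3.90 on the log2 scale, IFI44L by 3.43, MX2 by 3.32, IFIT1 by 2.33 and RSAD2 by 2.31. IFITM1 has the close paralogs IFITM2 and IFITM3, which rose by 0.39 and 1.21 and were named after their values were seen, and how reads shared between paralogs were counted was not given in the sources used here. Antigen presentation and interferon-gamma genes rose for 12 of 24 members and fell for 2, with 10 not passing (15 higher and 2 lower adjusted over the list alone). GBP1, an interferon-induced GTPase, rose from 0.752 ± 0.111 to 4.86 ± 0.356, and B2M, the shared light chain of HLA class I, rose from 566 ± 14.2 to 758 ± 14.1. The camera call of this list (adjusted p = 3.16e-05) was lost with an adjusted p = 0.204 with an estimated correlation. Of 29 JAK-STAT components, 2 rose and 9 fell (4 and 9 adjusted over the list alone), and camera made no call (adjusted p = 0.172). The feedback inhibitors SOCS2 and SOCS3 rose by 0.59 and 0.41, while STAT5B fell by 0.63 and the interferon receptor chain IFNAR2 fell by 0.33.

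NF-kB and inflammatory genes were lower in KO for 14 of 19 members, with 0 higher and 5 not passing (16 lower adjusted over the list alone), and a median log2 change of -1.09. The adaptor TRAF1 fell from 34.4 ± 0.543 to 7.04 ± 0.357, the chemokine IL8 from 56.1 ± 1.58 to 9.50 ± 0.765 and BIRC3, an inhibitor of apoptosis, from 37.9 ± 0.612 to 13.8 ± 0.288. SOD2, the mitochondrial superoxide dismutase, fell by 1.09. The camera adjusted p was 3.66e-13, and the adjusted p = 0.0393 with an estimated correlation.

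The genes lowest in KO relative to control included some near the detection limit in KO. RGS4, a regulator of G-protein signalling, went from 71.6 ± 0.197 to 0.069 ± 0.021, and the semaphorin SEMA7A from 58.5 ± 1.52 to 0.112 ± 0.037. STC1, a secreted glycoprotein hormone, fell from 424 ± 15.6 to 8.52 ± 0.058. SEMA3A fell by 3.83, SEMA3D fell by 3.86, CALB2 fell by 5.14, ADTRP fell by 4.75 and MAP1LC3C fell by 4.08. HBE1 was at 12.3 ± 1.32 in control and listed at 0 in both KO libraries. RP11-72L22.1, a non-coding gene, fell by 4.06. SUN3, a nuclear envelope protein, was the gene outside the interferon list among the 10 largest rises, from 20.5 ± 2.88 to 113 ± 1.998.

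Heat shock genes fell for 13 of 17 members and rose for 1, with 3 not passing (15 lower and 1 higher adjusted over the list alone). HSPA8, a constitutive chaperone, fell from 777.2 ± 56.5 to 395 ± 25.8, and the co-chaperone STIP1 fell by 0.60. The camera call (adjusted p = 1.2e-08) was lost with an adjusted p = 0.362 with an estimated correlation. Cell cycle genes fell for 19 of 44 members and rose for 2, with 23 not passing (24 and 2 adjusted over the list alone). The mitotic kinase PLK1 fell by 0.69, AURKA fell by 0.52 and the ribonucleotide reductase subunit RRM2 fell by 0.56 (camera adjusted p = 2.44e-08, adjusted p = 0.256 with an estimated correlation). Cholesterol synthesis genes fell for 8 of 23 members and rose for 2 (9 and 2 adjusted over the list alone), among them FDFT1, which fell by 0.55 (camera adjusted p = 0.00851, adjusted p = 0.241 with an estimated correlation). Epithelial and intestinal genes rose for 5 of 8 members (5 adjusted over the list alone), among them the keratins KRT8 and KRT18, by 0.66 and 0.41 (camera adjusted p = 0.01, adjusted p = 0.244 with an estimated correlation). Mitochondrially encoded genes fell for 3 of 13 members (3 adjusted over the list alone; camera adjusted p = 0.00191, adjusted p = 0.554 with an estimated correlation). Cytosolic ribosomal protein genes rose for 4 of 35 members (2 adjusted over the list alone; camera adjusted p = 0.0439, adjusted p = 0.554 with an estimated correlation).

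Other lists were not called by camera in KO against control. Of 15 YAP/TAZ-TEAD target genes, 1 rose and 1 fell (1 and 1 adjusted over the list alone; camera adjusted p = 0.8). CYR61 rose by 0.50, and CTGF fell from 3.52 ± 0.585 to 0.016 ± 0.022. AMOTL2 stood at 13.1 and 15.1 (adjusted p = 0.0501) and F3 at 3.71 and 2.83 (adjusted p = 0.133). Hippo pathway components fell for 2 of 19 members, WWTR1 and the kinase gene STK3 (1 adjusted over the list alone; camera adjusted p = 0.132). Stress response genes of the unfolded protein and integrated stress response list rose for 9 of 24 members and fell for 6 (9 and 6 adjusted over the list alone; camera adjusted p = 0.132). Those that rose include PSAT1 (by 1.25), SLC7A11 (by 2.28) and ASNS (by 1.71), which serve serine synthesis, cystine import and asparagine synthesis. Wnt target genes rose for 4 of 13 members and fell for 2 (4 and 2 adjusted over the list alone; camera adjusted p = 0.502), and the list's mean and median differed in sign. Epithelial-mesenchymal transition genes rose for 3 of 12 members and fell for 6 (3 and 6 adjusted over the list alone; camera adjusted p = 0.156). TAGLN and CALD1, actin-binding proteins, rose by 1.04 and 0.86, while VIM fell by 1.44 and TNC fell by 2.30. Among p53 target genes 6 of 26 rose and 4 fell (7 and 5 adjusted over the list alone; camera adjusted p = 0.502). Hypoxia and glycolysis genes rose for 8 of 23 members and fell for 4 (9 and 4 adjusted over the list alone; camera adjusted p = 0.156). Immediate early genes rose for 7 of 24 members and fell for 5 (7 and 7 adjusted over the list alone; camera adjusted p = 0.854). Replication-dependent histone genes fell for 2 of 10 members (1 adjusted over the list alone; camera adjusted p = 0.209). The libraries were of poly(A) RNA, so in every comparison histone transcripts without a poly(A) tail are not covered. Markers of other cell types were scarcely measured, with 1 blood and immune marker and 2 endothelial markers tested and 0 of them passing (0 adjusted over the list alone), and 0 fibroblast markers tested.

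In all, 2937 genes changed in KO against control, 1583 higher and 1354 lower, or 23.3% of those tested. The balance turned with median-of-ratios scaling, to 1419 higher and 1600 lower, and with a correction for GC content and length added after seeing the data, to 1697 higher and 1864 lower. At least 2-fold changes numbered 114 higher and 102 lower. The count was 1525 without control replicate 1, 1847 without control replicate 2, 1404 without KO replicate 1, 1494 without KO replicate 2 and 1948 with no filter on low values. Of 88 named genes past the test, 74 passed whichever library was left out, and those that did not include STK3, CLDN3, TJP1, ATP6 and ND2.

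The next comparison asked what differed between the cells labelled putback and those labelled KO. Interferon-stimulated genes fell in putback against KO for all 40 measured members (40 adjusted over the list alone), with a median log2 change of -0.95. OAS2 fell from 38.1 ± 1.69 to 2.74 ± 0.125, IFITM1 from 378 ± 2.91 to 39.9 ± 2.50, IFI6 from 338 ± 16.03 to 38.6 ± 3.19 and ISG15 from 618 ± 2.81 to 199.9 ± 10.9. OAS1 fell by 3.02, MX2 fell by 2.86, LGALS3BP fell by 2.68, IFI44L fell by 2.66 and IFI44 fell by 2.17. The camera adjusted p was 1.3e-44, and the adjusted p = 0.0334 with an estimated correlation. With a library left out, between 24 and 40 of the 40 members passed, the fewest without putback replicate 2.

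Antigen presentation and interferon-gamma genes fell for 12 of 24 members and rose for 0 (15 lower and 1 higher adjusted over the list alone). The HLA class I genes HLA-B fell by 1.08 and HLA-C fell by 0.52, and HLA-B stood at 61.4 ± 3.61 in putback, 131 ± 1.02 in KO and 112 ± 12.9 in control. HLA genes share near-identical stretches, so their reads are uncertain. The camera call (adjusted p = 5.2e-08) was lost with an adjusted p = 0.149 with an estimated correlation. Outside the fixed lists, ANXA1, a calcium-dependent phospholipid-binding protein, rose from 7.51 ± 1.12 to 28.1 ± 2.27 and the pseudogene transcript SFTA1P rose from 0.804 ± 0.393 to 4.43 ± 0.468. SLC15A3, a lysosomal peptide transporter, fell from 10.4 ± 0.080 to 2.06 ± 0.203. FOSL1, an AP-1 subunit, fell by 0.41. SLC25A6, which has close paralogs, averaged 76.4 ± 40.5 in KO and 19.9 ± 6.14 in putback, a change with large spread between the KO libraries. The largest rises also hold small RNA genes that lie within other genes, such as MIR6758 in MARS, SNORD14A in RPS13 and MIR641 in AKT2, whose reads cannot be separated from those of their hosts.

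Smaller shifts were found in other lists. Unfolded protein and integrated stress response genes rose for 7 of 24 members and fell for 1 (12 and 3 adjusted over the list alone; camera adjusted p = 0.00304, adjusted p = 0.393 with an estimated correlation). NF-kB and inflammatory genes fell for 3 of 19 members, TRAF1, NFKBIA and NFKBIE (4 adjusted over the list alone; camera adjusted p = 0.00304, adjusted p = 0.234 with an estimated correlation). Wnt target genes fell for 3 of 13 members, EPHB2, TCF7 and CCND1 (3 adjusted over the list alone; camera adjusted p = 0.00578, adjusted p = 0.393 with an estimated correlation). Camera made no call for the remaining lists. Of their members 1 rose and 3 fell among 29 JAK-STAT components (1 and 3 adjusted over the list alone), 1 rose and 1 fell among 15 YAP/TAZ-TEAD targets (1 and 2 adjusted over the list alone) and 2 rose among 19 Hippo components, WWTR1 and YAP1 (2 adjusted over the list alone). Among p53 target genes 5 of 26 rose (5 adjusted over the list alone), cell cycle genes fell for 2 of 44 (2 adjusted over the list alone) and immediate early genes rose for 1 and fell for 4 of 24 (1 and 6 adjusted over the list alone). Heat shock genes rose for 3 and fell for 2 of 17 (4 and 5 adjusted over the list alone), and ribosomal protein genes rose for 5 and fell for 3 of 35 (5 and 3 adjusted over the list alone). Epithelial-mesenchymal transition genes rose for 2 and fell for 1 of 12 (2 and 1 adjusted over the list alone), hypoxia and glycolysis genes fell for 3 of 23 (4 adjusted over the list alone), epithelial genes fell for 1 of 8 (1 adjusted over the list alone) and cholesterol synthesis genes rose for 1 of 23 (0 adjusted over the list alone). No mitochondrially encoded or histone gene passed. The mean, median and test differed in sign for the YAP/TAZ-TEAD, cholesterol, ribosomal and histone lists. The blood and immune marker CD68 fell by 0.28 (1 lower adjusted over the list alone) and the endothelial marker ESAM fell by 0.41 (2 lower adjusted over the list alone).

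The test passed for 1221 genes in putback against KO, 553 higher and 668 lower, with 16 higher and 44 lower at least 2-fold. This count depended strongly on single libraries and settings: it was 76 without KO replicate 1, 124 without KO replicate 2, 266 without putback replicate 1, 55 without putback replicate 2, 114 with no filter, 95 with a constant prior variance and 3198 with limma-voom on recovered reads, added after seeing the data. Of 69 named genes past the test, 16 passed whichever library was left out: WWTR1, ANXA1, SFTA1P, SLC15A3, FOSL1, HLA-B, HLA-C, ISG15, OAS1, OAS2, MX2, IFI6, IFI44, IFI44L, IFITM1 and LGALS3BP.

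Putback was then compared with control, to show which differences from control were present after putback. Interferon-stimulated genes were higher in putback than in control for 29 of 40 members, with 0 lower and 11 not passing (29 adjusted over the list alone), and a median log2 change of 0.44. IFI6 was higher by 1.42, LGALS3BP by 1.32, IFITM1 by 1.91 and OAS2 by 0.98. The camera call (adjusted p = 2.93e-11) was lost with an adjusted p = 0.13 with an estimated correlation. With a library left out, between 23 and 28 of the 40 passed, the fewest without putback replicate 2.

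NF-kB and inflammatory genes were lower in putback for 18 of 19 members (18 adjusted over the list alone), with a median of -1.09 (camera adjusted p = 1.6e-12, adjusted p = 0.0817 with an estimated correlation). TRAF1 stood at 4.34 ± 0.020, IL8 at 8.43 ± 0.628 and NFKBIA, the NF-kB inhibitor, at 42.0 ± 1.35 against 122 ± 2.82 in control. Several genes that had fallen in KO were low here too: RGS4 at 0.074 ± 0.057, SEMA7A at 0.110 ± 0.037, STC1 at 7.04 ± 0.374 and the collagenase MMP1 at 0.879 ± 0.127 against 26.0 ± 0.466 in control. Relative to control CALB2 fell by 5.43, MAP1LC3C fell by 4.84, ADTRP fell by 4.58, SEMA3D fell by 3.87 and the stromelysin MMP10 fell by 4.22. RP11-72L22.1 fell by 4.12. SLC7A11 rose from 3.02 ± 0.564 to 26.8 ± 1.89, SUN3 from 20.5 ± 2.88 to 122 ± 2.90 and LURAP1L by 2.41. MIR1304, a microRNA gene within TAF1D, was listed at 0 in control. MIR614 (within GPRC5A), SNORD54 (within RPS20), RNU7-71P (within ZFHX3) and C12orf39 were among the largest rises, each with fewer reads in every library than the median of 473 per tested gene.

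Unfolded protein and integrated stress response genes rose for 15 of 24 members and fell for 4 (16 and 4 adjusted over the list alone; camera adjusted p = 0.00373, adjusted p = 0.381 with an estimated correlation), and PSAT1 and ASNS were higher by 1.52 and 2.04. Heat shock genes fell for 12 of 17 members and rose for 1 (13 and 1 adjusted over the list alone; camera adjusted p = 5.04e-06, adjusted p = 0.427 with an estimated correlation), with HSPA8 at 375 ± 8.33. Cell cycle genes fell for 22 of 44 members and rose for 2 (26 and 2 adjusted over the list alone; camera adjusted p = 1.1e-06, adjusted p = 0.381 with an estimated correlation), where PLK1 fell by 1.01 and CDC20 fell by 0.67. Cholesterol synthesis genes fell for 8 of 23 members and rose for 1 (8 and 1 adjusted over the list alone; camera adjusted p = 0.0303, adjusted p = 0.381 with an estimated correlation). Mitochondrially encoded genes fell for 5 of 13 members (5 adjusted over the list alone; camera adjusted p = 0.0111, adjusted p = 0.564 with an estimated correlation). Camera made no call for the others. Antigen presentation genes rose for 5 and fell for 7 of 24 (5 and 7 adjusted over the list alone), where ICAM1 fell by 0.76 and HLA-B fell by 0.85. JAK-STAT components rose for 4 and fell for 10 of 29 (4 and 10 adjusted over the list alone), YAP/TAZ-TEAD targets rose for 3 and fell for 3 of 15 (3 and 3 adjusted over the list alone) and Hippo components rose for 3 and fell for 4 of 19 (3 and 4 adjusted over the list alone). CTGF was listed at 0 in both putback libraries, and CYR61 was higher than control by 0.40. Wnt targets rose for 2 and fell for 4 of 13 (2 and 4 adjusted over the list alone), p53 targets rose for 12 and fell for 2 of 26 (12 and 3 adjusted over the list alone), and epithelial genes rose for 4 of 8 (4 adjusted over the list alone). Epithelial-mesenchymal transition genes rose for 3 and fell for 7 of 12 (3 and 8 adjusted over the list alone), hypoxia and glycolysis genes rose for 4 and fell for 5 of 23 (4 and 5 adjusted over the list alone), and immediate early genes rose for 6 and fell for 10 of 24 (8 and 12 adjusted over the list alone). Ribosomal protein genes rose for 11 and fell for 3 of 35 (11 and 3 adjusted over the list alone) and histone genes rose for 1 and fell for 3 of 10 (1 and 3 adjusted over the list alone). The mean, median and test differed in sign for the antigen presentation, YAP/TAZ-TEAD and Hippo lists. Of the other cell types' markers, CD68 fell by 0.18 (1 lower adjusted over the list alone), and the endothelial markers ESAM fell by 0.46 and EGFL7 fell by 0.26 (2 lower adjusted over the list alone).

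**Figure D3:**
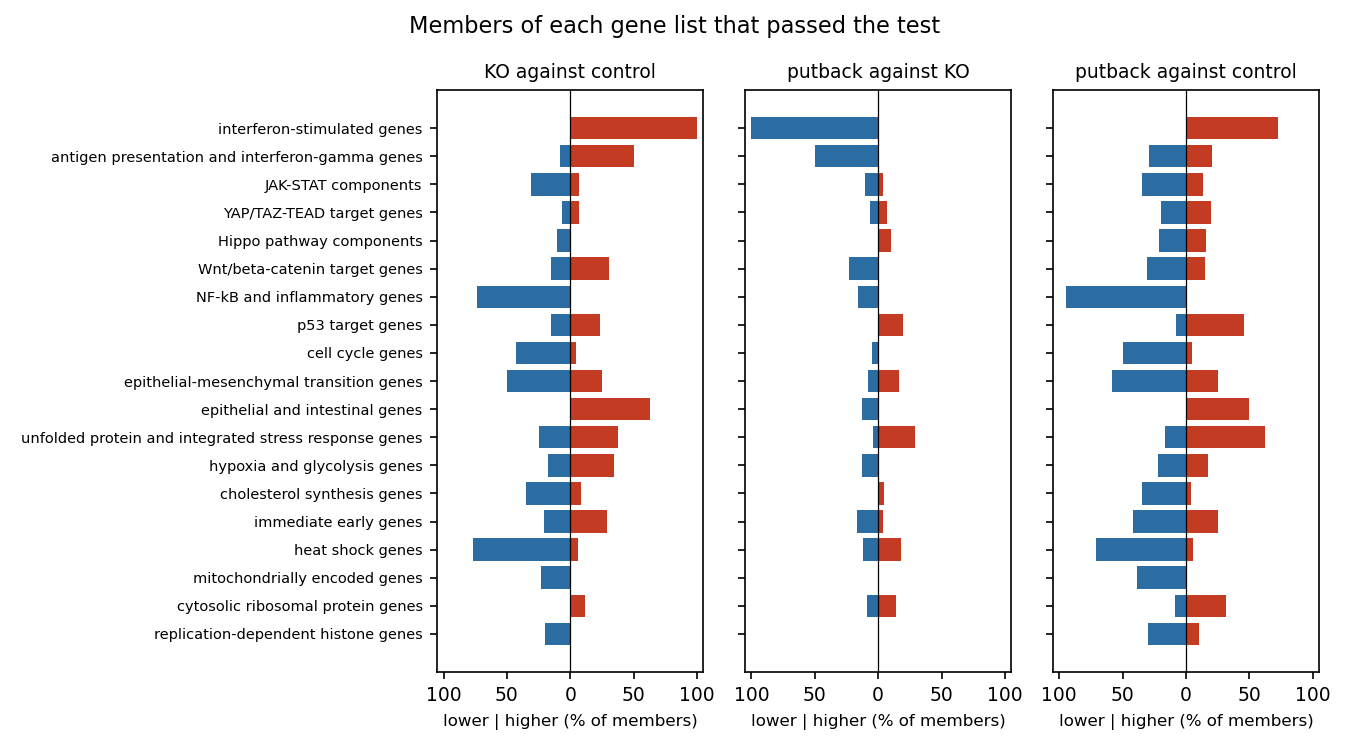
Percent of each list's measured members that passed the test as higher (right, red) or lower (left, blue) in each of the 3 comparisons, for the lists with at least 8 members. Interferon-stimulated genes were higher in KO for 40 of 40 members and lower in putback against KO for 40 of 40.

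In all 4628 genes differed between putback and control, 2318 higher and 2310 lower, with 98 higher and 108 lower at least 2-fold. With median-of-ratios scaling the split was 2124 higher and 2529 lower. The count was 3067 without control replicate 2 and 2482 without putback replicate 2. Of 96 named genes past the test, 78 passed whichever library was left out.

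The design also asks which KO changes moved the other way in putback. Of the 10 genes with the largest such changes, 8 were interferon-stimulated: OAS2, IFITM1, IFI6, OAS1, MX2, LGALS3BP, IFI44L and IFI44. The other 2, SLC25A6 and MIR6758, have uncertain reads. In total 270 genes changed in both comparisons in opposite directions, 177 higher in KO then lower in putback and 93 lower then higher, and 198 changed in the same direction. Both comparisons share the KO libraries. With unchanged simulated groups the opposite count averaged 0.1 and reached at most 1 in 100 simulated data sets. No gene changed in that simulation, so few could be called whatever the libraries shared, and its count is no chance value for the 270. Independent lists would share 83.8 and 59.3 genes in those directions. No such value was computed for the 198 genes, so an excess of opposite over same-direction changes was not tested. The covariance of the log2 changes was -0.02423 against -0.007859 simulated, a difference of -0.01637. The share of genes with opposite signs was 52.9% against 66.6% simulated, and the correlation across genes, which are not independent replicates, was -0.267 against -0.504 simulated. These 2 simulated values follow from the shared KO libraries alone when no gene changes. They are no chance values for data with changed genes, so the gaps to 52.9% and -0.267 tell nothing about reversal. The shared KO libraries may account for part of the excess over independent lists. The simulated covariance took in the spread between libraries of a group, but not a deviation common to both KO libraries. With 2 KO libraries these could not be split into parts of 2, so such a deviation may still add to the difference in covariance.

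Of the 2937 genes changed in KO, 2190 also differed between putback and control in the direction of KO, 1148 higher and 1042 lower. Both comparisons share the control libraries. Unchanged simulated groups gave 0.11 such genes on average and at most 1. Since no gene changed in that simulation, few could be called whatever the libraries shared, and its count is no chance value for the 2190. Independent lists would share 290.7 higher and 247.8 lower, values that leave out the shared control libraries. The covariance of these log2 changes was 0.1123 against 0.007718 simulated, a difference of 0.1046. The simulated covariance took in the spread between libraries of a group, but not a deviation common to both control libraries. The 2 control libraries could not be split into parts of 2, so such a deviation may still add to the difference in covariance. Putback lowered 11.2% of the genes raised in KO and raised 6.9% of those lowered in KO. Over all 12621 tested genes, 668 were lower and 553 higher in putback against KO. Among genes changed at least 2-fold in KO, 52 of 114 higher genes fell in putback and 13 of 102 lower genes rose. Of the 270 genes, 193 did not pass between putback and control. The count of 270 was 145 without control replicate 1, 51 without KO replicate 1, 64 without KO replicate 2, 110 without putback replicate 1, 45 without putback replicate 2, 58 with no filter and 406 at a mean FPKM of at least 5.

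**Figure D4:**
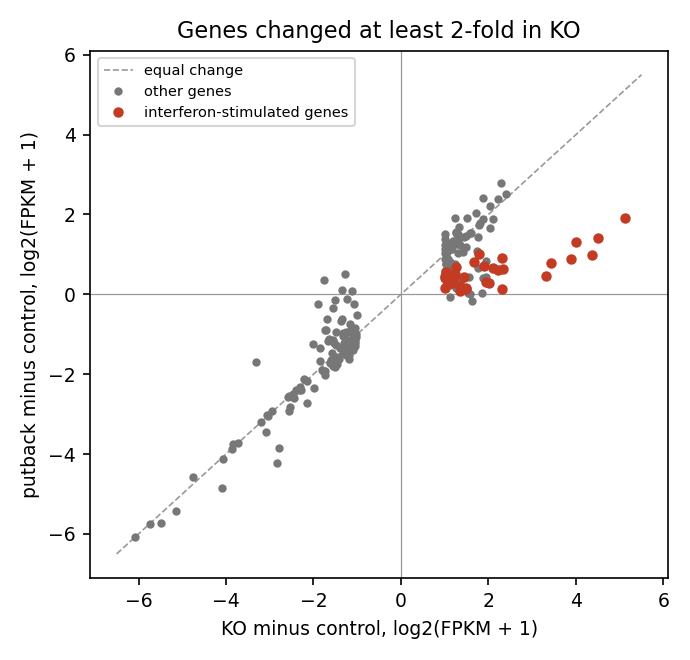
Log2 change in putback minus control (vertical) against KO minus control (horizontal) for the 216 genes changed at least 2-fold in KO, on the log2(FPKM + 1) scale, with the dashed line at equal change. The 33 interferon-stimulated genes (red) all lie below the line, and the other 183 are grey.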

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

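The alternatives run on the recovered reads, thinned reads, mRNA genes and the GC and length correction were chosen after the result was seen. No named gene and no list that camera called reversed direction. Lists without a call did change sign, with fry the YAP/TAZ-TEAD and histone lists in putback against KO and antigen presentation in putback against control. The balance of higher and lower genes in KO against control turned with median-of-ratios scaling (1419 and 1600) and with the GC and length correction (1697 and 1864). For putback against control the near-equal 2318 and 2310 became 2124 and 2529 with median-of-ratios scaling. WWTR1 kept its direction and stayed past the test in all 57 alternative fits over the 3 comparisons. The interferon-stimulated genes kept their direction and their camera call in each alternative, except that in putback against control the estimated correlation ended the call (median 0.44, adjusted p = 0.13). Camera with that correlation allows for genes moving together, but calls were also lost where the estimate was below 0. For cholesterol synthesis genes in KO against control it was -0.03, and the camera adjusted p went from 0.00851 to 0.241. A lost call therefore need not come from genes moving together. With an estimated correlation, camera tests on the residual degrees of freedom, 3 here, while the preset test uses a number set by the genes tested. For the NF-kB list in KO against control the estimate was -0.012, and the adjusted p went from 3.66e-13 to 0.0393. A call lost in this way is thus weak evidence against a list. Named genes passed or failed as before in 4223 cases, lost the test in 539 and gained it in 10. Gene lists kept theirs in 1248 cases, lost it in 38 and gained it in 37. The number of list calls, 21, became 3 with an estimated correlation and 37 with fry, which does not compare a list with other genes. The counts of changed genes moved most. For KO against control, 2937 became 1948 with no filter and 216 at 2-fold, and ranged from 1404 to 2505 with a library left out. For putback against KO, 1221 became 114 with no filter, 1951 at a mean FPKM of at least 5, 95 with a constant prior variance, 60 at 2-fold, 3198 with limma-voom, 2286 with mRNA genes only and 289 with the GC and length correction, and ranged from 55 to 875 with a library left out. For putback against control, 4628 became 206 at 2-fold and ranged from 2482 to 4328 with a library left out. The 270 genes changed in opposite directions became 58 with no filter, 406 at a mean FPKM of at least 5, 61 with a constant prior variance, 40 at 2-fold, 673 with limma-voom, 493 with mRNA genes only and 127 with the GC and length correction, and ranged from 45 to 186 with a library left out. A left-out library leaves a group with 1 sample, assumed to vary like the others, and fewer degrees of freedom; for the other shifts the cause was not tested. With the replicate number as a block, 366 genes passed in putback against KO and 120 changed in opposite directions. Same-numbered libraries did not deviate together (correlations -0.037, -0.026 and 0.071 across genes), so the numbers were not taken as pairs. Putback libraries were deeper, and thinning left the interferon counts at 40, 40 and 28.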

Other observations

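The mixing test on the interferon genes, all tests with thinned reads or the GC and length correction, and the tests on the chromosome 12 run were chosen after the result was seen; the mixing and copy number tests on the KO changes also found in putback were written before their values were seen. The genes BST2, IFIT2, LRP6, GPR19, GPRC5A, MANSC1, FAM208B and CCDC113 were chosen after their values were seen.

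As a list, interferon-stimulated genes in putback lay between control and KO, though 11 of the 40 did not pass between putback and control. If the putback cells held a fixed share of KO-like cells and the rest were like control, the share (putback minus control over KO minus control, in FPKM) would be equal over the list. Over 40 genes it ran from -0.23 (BST2, standard error 0.172) to 0.50 (IFIT2, standard error 0.07). The test of heterogeneity, which weighs each gene by its error, gave p = 4.99e-97 (chi-square 577.5 on 39 degrees of freedom). This argues against such a mix alone. The test cannot decide on a mix in which the other putback cells themselves differ from control. Depth and GC content with length are not the whole cause: 28 genes stayed higher than control after thinning and 29 after the correction. A partial return with gene-specific response to cTAZ is a hypothesis that these data leave open, since no other dose or time was measured.

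Of 2937 genes changed in KO, 2190 were changed the same way in putback against control. Independent lists would share 290.7 higher and 247.8 lower, values that leave out the shared control libraries. The 183 genes changed at least 2-fold in KO outside the interferon list had a median share of 0.997, against 0.123 for the list, a difference of 0.874 (95% bootstrap interval 0.778 to 0.919), which argues against a fixed share of KO-like cells among control-like cells. KO cells mixed with putback cells that kept the KO differences outside the interferon list could give the same values. The test therefore cannot decide on that mix. Of the 177 genes changed at least 2-fold in KO and the same way in putback, interferon genes included, 94.9% of those still tested stayed changed in both comparisons after thinning and 97.6% after the GC and length correction. Copy number over runs of 25 neighbours would touch many of them, but 0.62% of the 2107 same-way genes with a position lay in shifted runs. A shifted run needed an absolute median log2 change of at least 0.3, the same way in both comparisons, and 27 genes lay in one. Copy number differences that were smaller or spanned fewer genes would not register. A difference between the cell line from which KO and putback derive and the control, apart from cTAZ, may remain, but the labels do not describe how the lines were made, and this was not tested.

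Over 25 neighbouring genes the largest run median in KO against control was 0.405, on chromosome 12, above the highest of 100 permuted gene orders, 0.259. The core, from LRP6 to MIR614 (12116025 to 12917937, hg38), held 10 genes, 100% of them higher in both KO (8 past the test) and putback (7 past the test), GPR19, GPRC5A and MANSC1 among them, but MIR614 lies within GPRC5A, so its reads are not independent, and its call in putback was lost without either putback replicate; without it 9 genes remained (7 and 6 past the test), with medians of 0.391 in KO and 0.48 in putback. After the GC and length correction the core's medians were 0.344 and 0.385 (95% bootstrap intervals 0.196 to 0.706 and 0.115 to 0.556), without MIR614 0.33 and 0.365 (0.16 to 0.697 and -0.003 to 0.503), and over all 27 genes in shifted runs on that chromosome, 22 of them higher in both, 0.277 and 0.307 (0.125 to 0.477 and 0.136 to 0.41). The largest corrected run in KO was again on chromosome 12 at 0.413, above the highest of 100 permuted orders, 0.27, but not every interval lay above 0.1, so GC content and length stay open; that bound and the core were set after medians of the run had been seen, and an earlier bound of 0.3 on the medians was missed over all 27 genes in KO. A copy number difference between the cell lines could give this pattern, and cannot be told apart from regional regulation without DNA data, the genes having been picked for the run.

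On chromosome 10 the run centred on FAM208B had a median of -0.346 in KO and -0.252 in putback against control. The run centred on CCDC113 on chromosome 16 had medians of 0.272 and 0.207. In KO both also lay beyond 0.259, the highest absolute median of the 100 permuted gene orders, so chromosome 12 was not alone in this.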
